A study of Mus musculus with 14 samples.

How the data were processed

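RNA was measured in 14 libraries of sorted mouse synovial cells, per the labels: 4 of CD200+CD105- cells of non-immunized mice, 5 of the same phenotype from mice with antigen-induced arthritis, and 5 of CD200-CD105+ cells from arthritic mice. Per the labels' protocols, 200 to 500 cells per sample were lysed directly, ERCC spike-ins were added, cDNA was made with a SMART-Seq v4 kit, and Nextera XT libraries were read on a NextSeq 500. The submitters' processing notes name cutadapt, HISAT2, StringTie and edgeR, without versions, and the builds GRCm38 and mm10. The strand setting of the counting is not given in the sources used here, so antisense pairs could not be told apart.

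The deposited main table holds whole-number counts per gene, per the file headers and the values themselves, with 47821 entries, of which 92 are spike-ins and 47729 are genes. Gene symbols and positions came from GENCODE M21 (GRCm38), which matched 47310 gene IDs and left 419 without a symbol. At least 1 count was found for 25864 genes. A further deposited table is named as normalized and filtered, but its 14322 entries are identical to the raw counts of the same genes. Its lowest total was 51, while 18299 genes in the main table have a total over 50, so a total alone did not define it. It was used only as an alternative choice of genes. All columns mapped to a sample. Pairs of libraries of a group were checked for duplicates and none was found.

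Library sizes were the counts on genes, without spike-ins. Total counts per library ranged from 12177437 to 40331071, and 3 counts in 1 library equal 0.162 to 1.03 CPM. edgeR filterByExpr with a minimum count of 10 kept 15015 genes. Counts were scaled by TMM, and all 14 libraries entered 1 quasi-likelihood fit with 3 groups and robust shrinkage (common biological coefficient of variation 1.28, median prior degrees of freedom 2.99). Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 changes are approximate, computed as the absolute log2 change divided by the square root of the test's F statistic. Comparisons were arthritic against non-immunized CD200+ cells, CD105+ against CD200+ cells in arthritis, and arthritic CD105+ against non-immunized CD200+ cells. The groups, comparisons, tests, gene lists, the rule for naming genes and all alternatives but 2 were fixed before the data were examined. The 38 gene lists hold 624 genes, 622 of them in the table. Lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, again with the correlation estimated, and with fry.

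Genes named for the first 2 comparisons were the 10 with the largest and the 10 with the smallest log2 fold change among genes past the threshold, with a regular symbol, a mean of at least 10 CPM in the higher group and no overlap between groups. With fewer than 5 qualifying in a direction, the 5 with the smallest p were named instead, which applied to the first comparison in both directions. The third comparison used 5 and 5. For each list described, up to 4 members with the smallest p were followed, and the first of these in the order of p are named. Sort markers are named, and so are genes in which 1 library lay far from its group. Some single genes that these rules select are not reported here and were left out of that outlier test, while they stay in the gene lists and counts. Counts adjusted over the list alone used the Benjamini-Hochberg method within that list.

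Shares of libraries and summed CPM of 10 lists of other cell types were compared by exact permutation tests (126 splits for 5 against 4, 252 for 5 against 5), adjusted within families of 10 and 20 tests. Intervals of single shares are Wilson 95% intervals, and ratios with 1 to 3 counts in a group have Poisson-based 95% intervals. Folds against 0 counts use a floor of 3 counts over the group. Principal components used log2 CPM. The tests were checked on simulated data, with 50 genes changed at each of 4 sizes and the cell cycle list moved 4-fold. Simulated genes varied independently of each other.

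Alternatives were RLE factors, library sizes from the spike-ins, no filter, a strict filter of 10 CPM in 4 libraries, shrinkage without the robust option, a fit of only the 2 groups compared, DESeq2 with default filtering, limma voom with sample weights, and leaving out each library in turn. A run of limma on normalized values was planned but not made, since that table holds raw counts. After seeing the data, 2 alternatives were added, without the 3 libraries over 80% spike-ins and with the genes of the filtered table. Counts from other splits of the libraries used 100 of 126 distinct splits per comparison for edgeR and camera and 50 for DESeq2. The latter were drawn at random from the 100. Their number was lowered, for running time, after a run of all 100 had been seen, and they replace a run of the first 50 in order, in which every other split held library 1 in the group of 5. Neither earlier run excluded chance. Libraries far from their group were found with Dixon's ratio at 0.829 for 4 and 0.710 for 5 libraries, on log2 values plus 1 for genes and lists. A further list of 20 erythroid regulators and haem enzymes and one of 12 muscle progenitor genes were written after Gata1, Klf1 and Pax7 had been seen, and are used only in the closing tests. Haemoglobin genes were summed, since Hba-a1 and Hba-a2 share reads. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Reads and alignments are not analysed here, and no cell type was assigned to single cells, since each library is a pool.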

Results

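The data are RNA sequencing counts from small samples of sorted cells of the mouse knee synovium, the tissue that lines the joint cavity. Antigen-induced arthritis is a model in which mice immunized against a foreign albumin later receive the same protein into the joint. All animals were C57BL6 mice of 16 weeks, and the knees were taken 10 days after the joint injection. Every sample was negative for TER119 (a red cell marker), CD31 (an endothelial marker) and CD45 (a leukocyte marker), and positive for CD51, the integrin alpha V chain. CD200 and CD105 are surface proteins used to separate stages of skeletal progenitor cells. The 14 libraries form 3 groups. There are 4 libraries of CD200+CD105- cells from non-immunized mice, 5 of CD200+CD105- cells from arthritic mice, and 5 of CD200-CD105+ cells from arthritic mice, each made from 200 to 500 cells. Libraries are numbered 1 to 14 as in the labels. CD105+ cells of non-immunized mice are not analysed here, so the effect of arthritis on that population is not addressed. The labels do not say whether 2 samples of a group came from separate animals, nor whether the 2 arthritic populations share animals. So every p-value measures the spread between samples, taken as unpaired.

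In non-immunized CD200+ libraries 1 to 4 the total counts were 34692378, 36636155, 31424217 and 40331071. In arthritic CD200+ libraries 5 to 9 they were 34109149, 36382683, 23477780, 29209392 and 27212806. In arthritic CD105+ libraries 10 to 14 they were 12177437, 22228937, 21413574, 32024412 and 17938045. These totals include the added ERCC spike-in RNA. Counts on mouse genes ranged from 2919666 in library 6 to 18553803 in library 13. The number of genes with a count was 15183 ± 2221.5 (SD, n = 4) in non-immunized CD200+ cells, 14035.8 ± 3680.5 (n = 5) in arthritic CD200+ cells and 14932.6 ± 1934 (n = 5) in CD105+ cells. Expression levels are counts relative to each library's counts on mouse genes after TMM scaling (CPM), given as mean ± SD over the libraries of a group. A gene without a count in a group was compared with a floor of 3 counts over the whole group, which is 0.0540, 0.0577 and 0.0479 CPM in the same order of groups. Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

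Spike-ins took 59.8 ± 17.4% of all counts in non-immunized CD200+ cells, 63.7 ± 24.0% in arthritic CD200+ cells and 38.6 ± 15.8% in CD105+ cells. Neither difference exceeded the spread between libraries (two-sided exact permutation p = 0.897 and 0.111, 10 library measures tested, adjusted p = 0.897 and 0.278). The share was above 80% in 3 libraries, at 85.4% (Wilson 95% interval 85.3 to 85.4) in library 2, 87.4% (87.4 to 87.5) in library 5 and 91.98% (91.97 to 91.98) in library 6. Haemoglobin transcripts made up 8.21 ± 5.98% of gene counts in CD105+ cells, 0.224 ± 0.474% in arthritic CD200+ cells and 0.424 ± 0.394% in non-immunized CD200+ cells. They were higher in each of the 5 CD105+ libraries than in any arthritic CD200+ library (exact permutation p = 0.00794, the smallest this design can give, adjusted p = 0.0397). Mitochondrially encoded transcripts took 3.59 ± 0.945% in CD105+ cells against 6.52 ± 1.87% in arthritic CD200+ cells (exact permutation p = 0.00794, adjusted p = 0.0397). They took 5.37 ± 2.68% in non-immunized CD200+ cells.

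**Figure D1:**
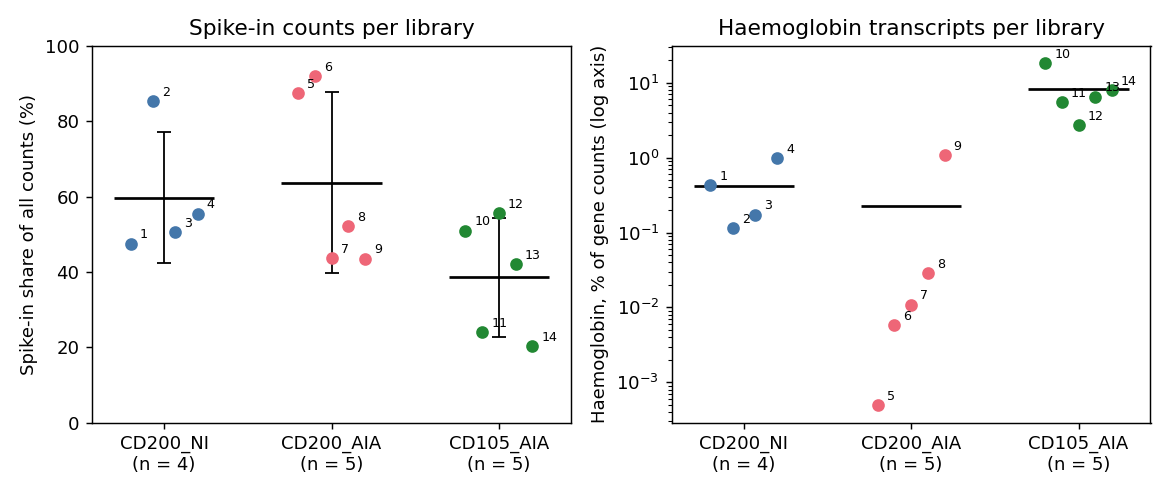
Share of spike-ins in all counts (left, percent, linear axis) and of haemoglobin transcripts in gene counts (right, percent, log axis) for the 14 libraries, each point 1 numbered library, horizontal bars the group mean and vertical bars on the left the SD. Libraries 2, 5 and 6 lie at 85.4%, 87.4% and 91.98% spike-ins, and the CD105+ libraries hold 2.71% to 18.3% haemoglobin.

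The populations separated on the first principal component of log2 CPM, which held 30.4% of the variance. CD105+ libraries lay between 147.86 and 248.06 on it and CD200+ libraries between -144.46 and -97.18. Non-immunized and arthritic CD200+ libraries overlapped on it only through library 5, at -125.54. The other arthritic ones lay at -100.7 or higher and the non-immunized ones at -107.24 or lower. On the second component, with 19.3% of the variance, libraries 5 and 6 lay highest at 219.26 and 284.78, with CD105+ library 10 at 94.54 and library 2 at 83.4. Across genes, the median Spearman correlation between libraries was 0.848 within CD105+ cells, 0.674 within non-immunized CD200+ cells and 0.627 within arthritic CD200+ cells. It was 0.667 between the 2 CD200+ groups and 0.502 between the 2 arthritic populations. Genes are not independent replicates, so these correlations carry no test.

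**Figure D2:**
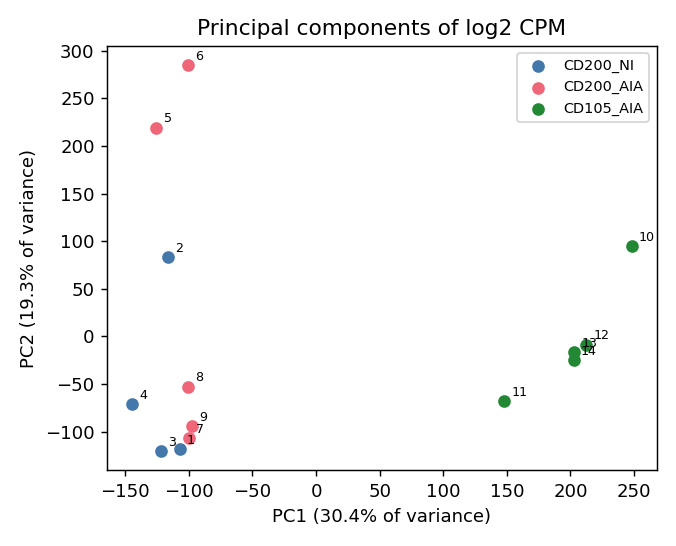
First and second principal components of log2 CPM (unitless scores), 1 numbered point per library, coloured by group. The CD105+ libraries sit at 147.86 or more on the first component and the CD200+ libraries at -97.18 or less, and libraries 5 and 6 stand apart on the second.

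Transcripts of the proteins used for sorting were set against the labels. Cd200 (ENSMUSG00000022661, GRCm38 chromosome 16, 45382135 to 45409053) was at 593 ± 178 CPM in non-immunized CD200+ cells, 420 ± 98.8 in arthritic CD200+ cells and 2.30 ± 5.14 in CD105+ cells. It fell by 7.50 on the log2 scale from arthritic CD200+ to CD105+ cells (edgeR adjusted p = 0.0123). Its 120 counts in CD105+ cells all came from library 12, and the other 4 libraries had none. Eng (ENSMUSG00000026814, chromosome 2, 32646595 to 32682669), which encodes CD105, was low in all groups, at 5.29 ± 5.71, 0.504 ± 0.584 and 6.63 ± 4.87 CPM. Its log2 difference between the arthritic populations was 3.64 and did not pass in edgeR (adjusted p = 0.170), while it passed in DESeq2 (adjusted p = 0.0363). It was at 0 CPM in CD105+ library 10, and highest of all libraries in CD105- library 1, at 12.3 CPM. Eng transcripts therefore do not bear out the CD105 label. Itgav, which encodes CD51, was at 32.3 ± 34.1, 35.9 ± 59.0 and 7.44 ± 9.57 CPM, and Thy1, which encodes CD90, at 4.35 ± 5.21, 4.43 ± 5.21 and 3.92 ± 4.52 CPM. Neither passed in either comparison, and the sign of both changed with scaling or when single libraries were left out. Pecam1, which encodes CD31, stood at 1.496 ± 1.34, 0.335 ± 0.123 and 0.621 ± 0.324 CPM. Ptprc, which encodes CD45, stood at 4.91 ± 9.83, 0.0151 ± 0.0338 and 6.90 ± 6.73 CPM. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 counts in all 14 libraries and Uty had 0, 1 and 4 counts per group, while Xist was at 71.7 ± 86.2, 121 ± 56.6 and 63.7 ± 59.4 CPM.

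The first comparison asks how CD200+ cells of arthritic and non-immunized mice differ, with 5 arthritic against 4 non-immunized libraries. Bone matrix transcripts were lower in arthritis as a set by limma camera with a preset correlation between genes, but not with the correlation estimated from the data (adjusted p = 0.769). Dmp1, a gene of late osteoblasts and osteocytes, averaged 199 ± 114 CPM in arthritic and 2310.4 ± 3467 in non-immunized cells. The latter mean rests on library 2 at 7432 CPM, with libraries 1, 3 and 4 at 1451, 113 and 246, and without library 2 the log2 change went from -3.54 to -1.62. Bglap, which encodes osteocalcin, averaged 576 ± 328 and 3462 ± 2591. The type I collagen genes Col1a2 and Col1a1 averaged 2943 ± 2132 and 936 ± 1078 CPM in arthritis against 9718 ± 4771 and 3269 ± 1581 without it. Cell cycle transcripts were higher as a set in the same way, and again not with an estimated correlation (adjusted p = 0.802). Tyms, needed for DNA synthesis, was at 53.6 ± 15.0 against 23.3 ± 13.6 CPM and Pcna at 206 ± 74.8 against 97.8 ± 35.2. No single gene passed the threshold, so none of these members is a call by itself. Each library is a pool, and muscle and mural cell markers were found in both groups. For every list of this comparison, a difference in cell make-up cannot be told apart from a change within like cells.

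Of 38 gene lists fixed beforehand, 34 had at least 5 tested members, and 11 of these passed limma camera's two-sided test with the preset correlation of 0.01, 3 of them up and 8 down. With the correlation between genes estimated from the data, 0 passed, and fry, which tests whether a list's genes move on balance one way, passed 0 with a lowest adjusted p of 0.424. All 20 osteoblast lineage members were lower (median log2 change -1.76, camera adjusted p = 5.34e-07; adjusted p = 0.769 with an estimated correlation). Of the 30 cell cycle members 26 were higher (median 1.04, camera adjusted p = 0.000268; adjusted p = 0.802 with an estimated correlation), a number that is 23 with RLE factors and 28 with spike-in scaling. Of the 28 oxidative phosphorylation members, nuclear genes of the respiratory chain, 23 were higher (median 0.52, camera adjusted p = 2.27e-06; adjusted p = 0.769 with an estimated correlation). With RLE factors 19 of them were higher (median 0.37) and with spike-in scaling 25 (0.63). Ndufs3 stood at 190 ± 80.2 against 82.5 ± 26.0 CPM and Ndufa5 at 272 ± 59.3 against 133 ± 43.3. Of the 36 ribosomal protein genes 34 were higher (median 0.30, camera adjusted p = 5.38e-05; adjusted p = 0.802 with an estimated correlation), such as Rps19 at 2804 ± 1246 against 1589 ± 433 CPM. With RLE factors 31 were higher (median 0.14) and with spike-in scaling all 36 (0.42). These 4 lists passed without any 1 of the 9 libraries, with highest adjusted p of 6.07e-05, 0.0266, 0.000470 and 0.0237. Apart from the erythroid list, 0 members of the 11 lists passed when adjusted over the list alone. Without library 3 or 5, 7 lists passed, and 6 without library 9. Without the 3 libraries over 80% spike-ins, a setting chosen after the data were seen, 14 lists passed, 9 of them among the 11. The immediate early and protease lists no longer did (adjusted p = 0.582 and 0.166). Newly past were skeletal muscle and glycolysis as higher (0.0106 and 0.0206) and macrophage, stromal progenitor and synovial sublining as lower (0.0170, 0.0206 and 0.0209). With an estimated correlation 0 passed there too, the lowest being cell cycle at 0.0729.

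**Figure D3:**
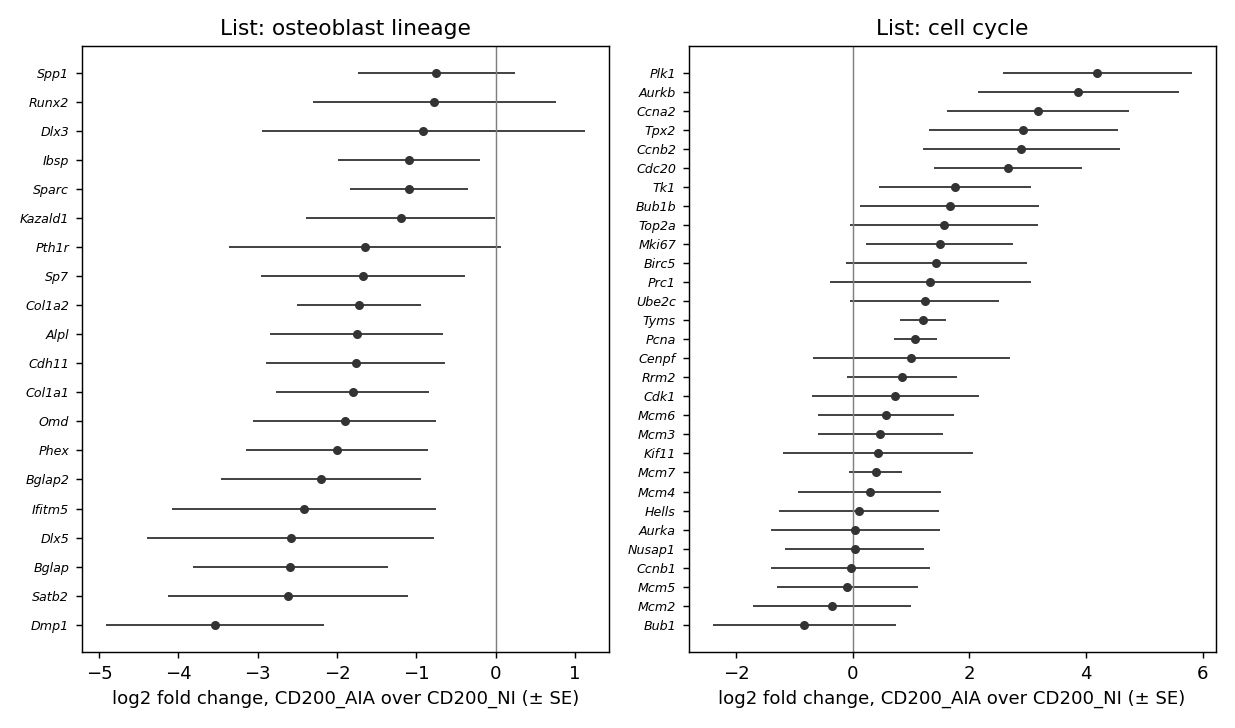
Log2 fold change of each tested member of the osteoblast lineage list (left, 20 genes) and the cell cycle list (right, 30 genes), arthritic over non-immunized CD200+ cells. Points are the edgeR estimate and bars an approximate standard error, computed from the estimate and the test's F statistic. All 20 osteoblast lineage members lie below 0, as they also do with RLE factors or spike-in library sizes, and 26 cell cycle members lie above 0 (23 with RLE factors, 28 with spike-in library sizes).

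Lists of matrix and skeletal signalling passed less firmly. Of the 28 extracellular matrix members 25 were lower (median -0.69, camera adjusted p = 0.0119; adjusted p = 0.802 with an estimated correlation), with the tenascin gene Tnc at 390 ± 357 against 1846 ± 1673 CPM. Of 23 Wnt pathway members 18 were lower (median -1.38, camera adjusted p = 0.0136; adjusted p = 0.802 with an estimated correlation), with the secreted Wnt inhibitor gene Wif1 at 94.5 ± 80.6 against 431 ± 306 CPM. Of 18 cartilage members 16 were lower (median -2.56, camera adjusted p = 0.0216; adjusted p = 0.802 with an estimated correlation). Chad, a cartilage matrix gene, stood at 90.1 ± 74.3 against 915 ± 427 CPM, and the matrilin gene Matn3 at 3.61 ± 8.07 against 127 ± 149. Of 20 matrix protease and inhibitor genes 16 were lower (median -0.98, camera adjusted p = 0.0370; adjusted p = 0.802 with an estimated correlation). The cathepsin gene Ctsb stood at 517 ± 86.7 against 1012 ± 673 CPM and the procollagen protease gene Adamts2 at 91.0 ± 37.8 against 223 ± 104. Mmp3, which encodes stromelysin, went the other way at 1336 ± 2142 against 6.70 ± 8.30 CPM, and did not pass in edgeR (log2 change 7.62, adjusted p = 0.914). The matrix list no longer passed without library 3, 4 or 6 (highest adjusted p 0.111), the Wnt list without 3, 5 or 9 (0.111), the cartilage list without 1, 3, 5 or 9 (0.284), and the protease list without any library but 8 (0.309). Directions held with RLE and spike-in scaling in each, with 25 and 21 matrix, 20 and 17 Wnt, 16 and 17 cartilage, and 16 and 16 protease members lower.

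The remaining lists that passed concern immediate early and immune genes. All 20 members of the immediate early and dissociation list, genes induced within minutes by stress or enzyme digestion, were lower (median -1.57, camera adjusted p = 0.00243; adjusted p = 0.802 with an estimated correlation; 18 lower with spike-in scaling). Junb stood at 584 ± 184 against 3536 ± 5568 CPM and Jund at 88.4 ± 33.6 against 669 ± 989. This list rested on library 2, since without it the sign reversed (adjusted p = 0.953), and it also no longer passed without library 9. The 5 tested MHC class II genes were lower (median -3.92, camera adjusted p = 0.0216; adjusted p = 0.802 with an estimated correlation), among them Cd74 at 1.05 ± 0.846 against 227 ± 260 CPM and H2-Ab1 at 12.5 ± 21.5 against 192 ± 227. Summed markers of B and plasma cells were lower in the same comparison (8.50 ± 13.0 against 1749 ± 3362 CPM, exact permutation p = 0.00794, adjusted p = 0.0265). They stood at 6791 CPM in library 3 and 31.6 to 87.8 in the other 3 non-immunized libraries. Of these cells, B cells also express MHC class II genes. A change within the sorted cells is therefore not shown. That list no longer passed without library 3, 4, 5 or 9 (highest adjusted p 0.158). Of 9 erythroid members 8 were lower (median -1.27, mean -4.40, camera adjusted p = 0.00106; adjusted p = 0.802 with an estimated correlation), but not without library 1 (0.0536). Of these, 4 passed as lower when adjusted over the list alone and 0 over all genes, and each of the 4 had 0 counts in arthritic CD200+ cells. The erythroid transcription factor gene Klf1 was at 10.0 ± 12.9 CPM in non-immunized cells and at least 174-fold lower in arthritis, or 75.2-fold without library 2, which held 67.6% of its CPM.

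The other 23 lists did not pass with all libraries, with camera adjusted p from 0.0891 for mitochondrially encoded mRNA to 0.980 for mural cells. Interferon response was at 0.126, skeletal muscle at 0.168, stromal progenitor at 0.176, BMP and TGF-beta at 0.224, osteoclast at 0.228, and neutrophil and osteoclast regulators at 0.273. Macrophage was at 0.407, unfolded protein response at 0.457, endothelial at 0.546, Notch at 0.771, and adipogenic and synovial sublining at 0.882. Synovial lining, glycolysis, immune suppression, tendon and Schwann were at 0.884, MHC class I at 0.912, hypoxia at 0.923, and cytokines and chemokines at 0.976. For the adipogenic, lining, glycolysis, immune suppression and MHC class I lists the median and mean were negative while the test's direction was up, and for the sublining, hypoxia and mural lists the median and mean differed in sign. Of the lining genes with the smallest p, Tspo2 had 0 counts in arthritis and 2.18 ± 4.36 CPM without it, all from library 1. Prg4, the lubricin gene of lining fibroblasts, stood at 793 ± 863 CPM in arthritis against 39.9 ± 38.2 and did not pass in edgeR (log2 change 4.31, adjusted p = 0.900). Adjusted over the list alone, 1 endothelial gene was higher, and 2 sort marker genes, 1 T and NK gene and 2 B and plasma genes were lower.

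Gene by gene, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 15015 genes (lowest adjusted p = 0.636). At an unadjusted p under 0.05 there were 915 genes, 483 higher and 432 lower, against 750.75 by chance. DESeq2 called 224 (80 higher, 144 lower) and limma voom with sample weights 4, and edgeR without library 3 called 2. The groups did not overlap for 344 genes, 2.29% of those tested, where chance gives 1.59%. The genes with the smallest p, none past the threshold (edgeR adjusted p = 0.636), were led among the higher ones by Cryab, which encodes a small heat shock protein (ENSMUSG00000032060, chromosome 9, 50751325 to 50756636). It stood at 500 ± 163 against 136 ± 52.2 CPM (log2 change 1.87, SE 0.38) and was higher in each of the 5 arthritic libraries than in any of the 4 others. Sh3glb1 stood at 378 ± 119 against 167 ± 27.7 CPM and Tipin, a replication fork gene, at 172 ± 51.9 against 54.0 ± 19.6. Trmt5 at 20.4 ± 18.9 and Tedc2 at 11.4 ± 12.3 CPM had 0 counts in non-immunized cells, so they were at least 377-fold and 212-fold higher, or 240.01-fold and 127-fold without library 6 and 8. Among the lower ones, Samhd1 stood at 20.6 ± 10.3 against 102 ± 62.1 CPM. Kyat1, Tiam1, Nxpe2 and Tspan32 had 0 counts in arthritis and 14.6 ± 13.7, 2.88 ± 2.02, 4.51 ± 6.44 and 7.41 ± 7.38 CPM without it, so they were at least 253-fold, 49.9-fold, 78.1-fold and 128-fold lower. Without library 2 the bound for Kyat1 was 145-fold, without library 1 that for Nxpe2 22.9-fold, and without library 4 that for Tspan32 77.2-fold.

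The gene test of this comparison was tried on simulated counts, with 50 genes changed at each of 4 sizes among 15015. The test recovered 0% at 2-fold and at 4-fold, 12% at 8-fold and 20% at 16-fold, with 0 false calls. Few genes were changed, which makes the adjusted threshold strict, and simulated gene means were averages over all 3 groups. These shares therefore do not give the power of this comparison. A simulated 4-fold change of the 30 cell cycle genes was called by camera with the preset correlation. It was larger than the observed median log2 change of 1.04. Simulated genes varied independently, while the estimated correlation of this list in the data was 0.47. This call therefore does not bear on whether the preset correlation suits the data. Against the TMM scale, the median log2 change of all genes shifted by -0.17 with RLE factors and by 0.17 with spike-in library sizes.

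The second comparison asks how CD105+ cells differ from CD200+ cells in the arthritic joint, with 5 libraries each. Of 20 osteoblast lineage genes, 11 passed as lower in CD105+ cells, while the list as a set did not pass with an estimated correlation (adjusted p = 0.146). Ibsp, which encodes bone sialoprotein (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469), was at 2866 ± 1668 CPM in CD200+ and 0.161 ± 0.235 in CD105+ cells (log2 change -13.98, SE 1.45, edgeR adjusted p = 9.58e-05). Spp1, which encodes osteopontin, was at 29877 ± 7271 CPM in CD200+ and 43.9 ± 58.2 in CD105+ cells (log2 change -9.41, edgeR adjusted p = 0.000856). Of 9 erythroid marker genes, 6 passed as higher, and again the set did not pass with an estimated correlation (adjusted p = 0.146). Gata1, the transcription factor of erythroid and megakaryocytic cells (ENSMUSG00000031162, chromosome X, 7959260 to 7978071), was at 303 ± 105.04 CPM in CD105+ cells with 0 counts in arthritic CD200+ cells, at least 5247-fold higher (edgeR adjusted p = 0.000105). Pax7, the transcription factor of muscle stem cells (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), went the other way, with 0 counts in CD105+ cells and 295 ± 116 CPM in CD200+ cells, at least 6157-fold lower (edgeR adjusted p = 4.14e-05).

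Of the 34 lists tested, 19 passed limma camera, 4 up and 15 down in CD105+ cells. With an estimated correlation 0 passed, and fry passed 18, of which 15 were among the 19. Without the 3 libraries over 80% spike-ins, a setting chosen after the data were seen, the osteoblast lineage, BMP and TGF-beta, and cell cycle lists passed with an estimated correlation (adjusted p = 0.00958, 0.0154 and 0.0384). All 30 cell cycle genes were higher in CD105+ cells, of which 9 passed the threshold (median log2 change 3.71, camera adjusted p = 7.37e-14; adjusted p = 0.146 with an estimated correlation). The helicase gene Mcm7 rose from 42.0 ± 21.8 to 666 ± 228 CPM (edgeR adjusted p = 0.000210) and Pcna from 206 ± 74.8 to 1358 ± 463 (adjusted p = 0.000436). All 9 erythroid members were higher and 6 passed (median 6.74, camera adjusted p = 3.72e-08; adjusted p = 0.146 with an estimated correlation). Smaller shifts upward were found for 27 of 28 oxidative phosphorylation genes (median 0.60, camera adjusted p = 0.00290; adjusted p = 0.364 with an estimated correlation) and for 35 of 36 ribosomal protein genes (median 0.54, camera adjusted p = 0.00278; adjusted p = 0.735 with an estimated correlation). Cyc1, which encodes cytochrome c1, rose from 219 ± 79.7 to 617 ± 91.0 CPM (edgeR adjusted p = 0.00768). Rps2 rose from 856 ± 380 to 2107 ± 360 CPM (edgeR adjusted p = 0.0218), a call that ended without library 9 or library 14 (highest adjusted p 0.0559). Adjusted over the list alone, 25 cell cycle, 9 erythroid, 8 oxidative phosphorylation and 2 ribosomal genes rose, against 9, 6, 4 and 3 over all genes.

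Skeletal and stromal lists were lower by camera. Erythroid genes were higher in CD105+ cells and muscle genes in CD200+ cells, and each library is a pool. For every list of this comparison, a difference in cell make-up cannot be told apart from a difference within like cells. This includes the higher cell cycle, oxidative phosphorylation and ribosomal lists above. All 20 osteoblast lineage genes were lower, 11 past the threshold and 16 adjusted over the list alone (median -4.70, camera adjusted p = 4.77e-11; adjusted p = 0.146 with an estimated correlation). Of 28 BMP and TGF-beta pathway genes 25 were lower and 14 fell, 15 adjusted over the list alone (median -3.97, or -3.94 with genes at 0 set to their bound, camera adjusted p = 1.53e-10; adjusted p = 0.0517 with an estimated correlation). The BMP target gene Id3 was at 1867 ± 340 CPM in CD200+ and 111 ± 94.3 in CD105+ cells (edgeR adjusted p = 0.000361), and Bmp4 at 144 ± 83.0 and 0.356 ± 0.680 (adjusted p = 0.000678). Of 18 stromal progenitor genes 16 were lower and 4 fell, 5 adjusted over the list alone (median -2.51, camera adjusted p = 0.000953; adjusted p = 0.278 with an estimated correlation). Kitl, the stem cell factor gene, went from 86.5 ± 25.5 to 0.297 ± 0.664 CPM (edgeR adjusted p = 0.00453) and the leptin receptor gene Lepr from 185 ± 82.3 to 1.56 ± 2.16 (adjusted p = 0.0121). All 9 tendon and ligament genes were lower, with 1 fallen and 2 adjusted over the list alone (median -2.02, camera adjusted p = 0.0178; adjusted p = 0.333 with an estimated correlation), but not without library 8 (0.0534). Chodl in that list went from 657 ± 455 to 0.799 ± 1.44 CPM (edgeR adjusted p = 0.00150). Of 10 adipogenic genes 7 were lower, with only Adipoq past, also when adjusted over the list alone (median -3.03, or -0.57 with spike-in scaling, camera adjusted p = 0.00496; adjusted p = 0.170 with an estimated correlation).

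The matrix and protease lists were lower by camera too, although most members did not pass. Of 28 extracellular matrix genes 26 were lower, 20 with spike-in scaling, and 2 fell, 1 adjusted over the list alone (median -1.54, or -0.54 with spike-in scaling, camera adjusted p = 0.000402; adjusted p = 0.419 with an estimated correlation). Tnc went from 390 ± 357 to 6.76 ± 7.49 CPM (edgeR adjusted p = 0.0167), a call that ended with limma voom (0.0845) and with spike-in library sizes (0.128). Of 20 matrix proteases and inhibitors 17 were lower and 5 fell, 8 adjusted over the list alone (median -1.97, or -0.69 with spike-in scaling, camera adjusted p = 6.27e-05; adjusted p = 0.146 with an estimated correlation). Mmp13, a collagenase gene, went from 1640.3 ± 1530 to 0.172 ± 0.243 CPM (edgeR adjusted p = 0.000109) and Ctsl from 749 ± 302 to 162 ± 61.1 (adjusted p = 0.00254). Mitochondrially encoded mRNA was lower for 12 of 13 genes and 3 fell, 5 adjusted over the list alone (median -0.80, camera adjusted p = 0.00715; adjusted p = 0.521 with an estimated correlation), but with spike-in scaling 10 of the 13 were higher and the median was 0.25. Nuclear copies of these genes share sequence with them, so their counts are uncertain.

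Signalling lists were lower by camera as well. All 20 immediate early and dissociation genes were lower, 18 with spike-in scaling, and 9 fell, 15 adjusted over the list alone (median -3.63, camera adjusted p = 9.06e-12; adjusted p = 0.146 with an estimated correlation). Fosb went from 685 ± 546 to 14.0 ± 11.5 CPM (edgeR adjusted p = 0.00198) and the heat shock gene Hspa1a, which shares reads with Hspa1b, from 811 ± 512 to 45.8 ± 35.4 (adjusted p = 0.00232). Of 13 Notch pathway genes 10 were lower and 6 fell, 8 adjusted over the list alone (median -3.87, camera adjusted p = 2.74e-05; adjusted p = 0.146 with an estimated correlation). Notch3 went from 89.8 ± 25.4 to 1.09 ± 2.12 CPM (edgeR adjusted p = 0.00955). Of 15 cytokine and chemokine genes 11 were lower, 8 with spike-in scaling, and 5 fell, as when adjusted over the list alone (median -2.13, camera adjusted p = 0.000806; adjusted p = 0.170 with an estimated correlation). Csf1, the macrophage growth factor gene, went from 72.7 ± 22.4 to 5.96 ± 4.95 CPM (edgeR adjusted p = 0.00595) and Cxcl14 from 140 ± 49.3 to 6.27 ± 7.84 (adjusted p = 0.0109). All 8 osteoclast regulators were lower and 3 fell, 4 adjusted over the list alone (median -3.64, camera adjusted p = 0.0129; adjusted p = 0.182 with an estimated correlation). Of 23 Wnt pathway genes 20 were lower and 3 fell, 4 adjusted over the list alone (median -1.94, camera adjusted p = 0.0138; adjusted p = 0.475 with an estimated correlation), but not without library 7 (0.0504). Sfrp4, a secreted Wnt inhibitor gene, went from 452 ± 152 to 42.8 ± 39.2 CPM (edgeR adjusted p = 0.00361), and Wif1 had 0 counts in CD105+ cells, at least 1974-fold lower (adjusted p = 0.00434).

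Lists of other cell types that a skeletal progenitor sort need not hold also moved. Of 11 skeletal muscle genes 10 were lower in CD105+ cells and 4 fell, 7 adjusted over the list alone with 1 risen (median -6.49, camera adjusted p = 3.72e-05; adjusted p = 0.170 with an estimated correlation). Myod1, a myoblast transcription factor gene, was at 168.5 ± 90.6 CPM in CD200+ cells with 2 counts in CD105+ cells (edgeR adjusted p = 0.000127). All 10 mural cell genes were lower and 3 fell, 6 adjusted over the list alone (median -4.63, camera adjusted p = 0.000625; adjusted p = 0.170 with an estimated correlation), such as Des, which muscle also expresses, from 181 ± 96.5 to 2.93 ± 3.19 CPM (edgeR adjusted p = 0.00844). The 15 lists that did not pass had camera adjusted p of 0.0506 for hypoxia, 0.0514 for immune suppression, 0.0604 for unfolded protein response, 0.109 for cartilage, and 0.625 for endothelial, osteoclast and MHC class II. Sublining was at 0.720, lining at 0.764, interferon response at 0.783, glycolysis at 0.812, macrophage at 0.899, neutrophil at 0.905, Schwann at 0.974 and MHC class I at 0.988. For the endothelial, lining, interferon and glycolysis lists the signs of the median, mean and test differed. Within the lining list Vcam1, an adhesion gene, fell from 834 ± 199 to 21.0 ± 11.2 CPM (edgeR adjusted p = 3.63e-05), while Tspo2 in the same list rose and is also known from erythroid cells. For the T and NK, B and plasma, sex chromosome and sort marker lists, 1, 0, 0 and 1 genes rose and 0, 0, 0 and 1 fell, and their sets were not tested.

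Gene by gene, edgeR's quasi-likelihood test called 1692 of 15015 genes, 719 higher and 973 lower in CD105+ cells (lowest adjusted p = 1.72e-05), of which 493 had 0 counts in the lower group. Groups did not overlap for 2518 genes, 16.8% of those tested, where chance gives 0.794%. The 10 genes with the largest rise came from 490 with no overlap between the groups, and several are known from the red cell lineage. Those reported here besides Gata1 were Ctse at 2866 ± 1534 CPM (at least 49639-fold higher), the blood group gene Rhd at 1281 ± 505 (22185-fold), Klf1 at 968 ± 369 (16761-fold), the amino acid carrier gene Slc38a5 at 656 ± 260 (11360.5-fold), Nxpe2 at 429.7 ± 139.9 (7442-fold), Tspo2 at 325 ± 75.6 (5637-fold) and Gfi1b at 293 ± 165 (5076-fold), each with 0 counts in arthritic CD200+ cells. Car1, a red cell carbonic anhydrase gene, was at 3429 ± 2201 CPM with 2 counts in arthritic CD200+ cells, a ratio of 89093 with a 95% counting interval of 24664 to 735672. Their edgeR adjusted p lay between 0.000105 and 0.00984. The 10 with the largest fall, from 573 without overlap, included Ibsp and 9 genes with 0 counts in CD105+ cells. Beside Pax7 these were the fat cell hormone gene Adipoq at 534 ± 648 CPM in CD200+ cells (at least 11158.5-fold lower), Cavin2 at 329.9 ± 163 (6888-fold), Asb5 at 259 ± 293 (5403-fold), the muscle acetylcholine receptor gene Chrnb1 at 207 ± 93.2 (4314-fold), the muscle cadherin gene Cdh15 at 192 ± 91.3 (4016-fold), the Notch target Heyl at 160.4 ± 103 (3350-fold), Kng1 at 158 ± 142 (3308-fold) and Ptprd at 153 ± 96.2 (3193-fold). Without their highest library the bounds were 5227.5-fold for Adipoq, 2892-fold for Asb5 and 2080-fold for Kng1. Their edgeR adjusted p lay between 4.14e-05 and 0.00160.

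**Figure D4:**
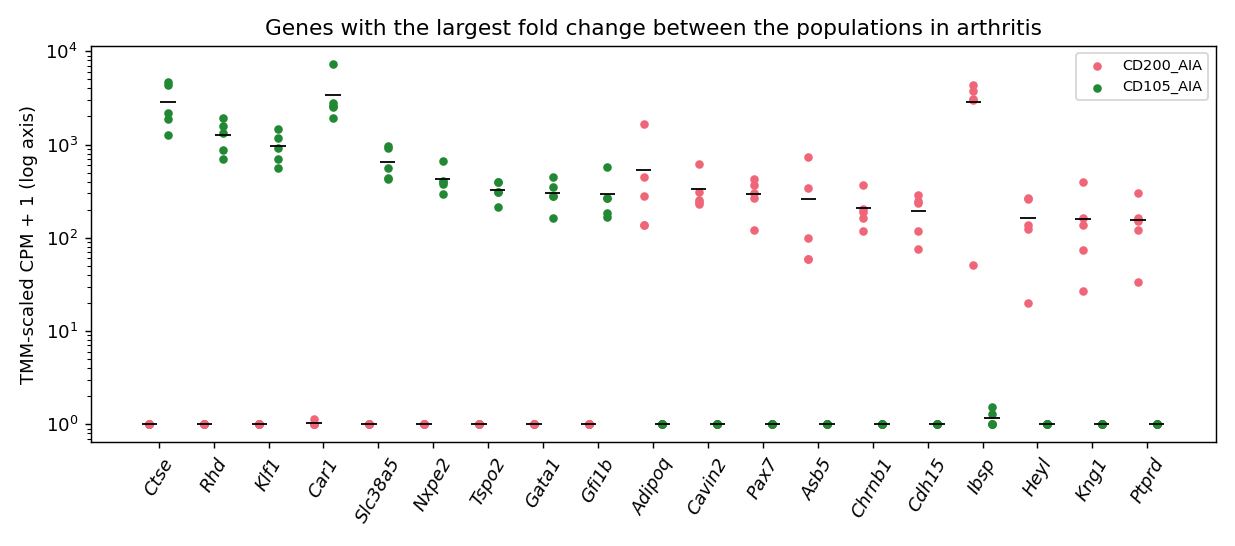
TMM-scaled CPM plus 1 (log axis) of 19 genes among those with the largest fold changes between the arthritic populations, each point 1 of 5 libraries per group and bars the group mean. The 9 genes on the left are at 293 CPM or more on average in CD105+ cells, and the 10 on the right at 153 CPM or more in CD200+ cells.

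DESeq2 called 3274 genes, limma voom 4624 and edgeR with spike-in library sizes 545, of which 390 were higher and 155 lower, and without library 14 edgeR called 1090. With only the 2 groups fitted, edgeR called 1396, of which 733 were higher and 663 lower. The balance of directions thus depends on the fit. Spike-in scaling shifted the median log2 change of all genes by 1.23, and RLE factors by -0.09. Of 76 named or followed genes past the threshold, 34 no longer passed with spike-in library sizes, among them Id3, Lepr, Tnc, Ctsl, Fosb, Notch3, Csf1, Cxcl14, Sfrp4, Cyc1, Rps2 and Des, and 2, both mitochondrially encoded, changed sign. The median of each list past the test kept its sign with both scalings, except for mitochondrially encoded mRNA with spike-in sizes, but with those sizes the medians of most lower lists moved toward 0, and those of the ribosomal and oxidative phosphorylation lists rose to 1.89 and 1.87. The test recovered 24% of simulated 8-fold and 26% of 16-fold changes, and 0% of 2-fold and 4-fold ones, with 1 false call. Few genes were changed in that simulation, which gave 26 calls against the 1692 of the data. The adjusted threshold was therefore stricter there, and these shares do not give the power of this comparison.

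The third comparison sets arthritic CD105+ cells against non-immunized CD200+ cells, where population and disease differ together and neither can be singled out. Gene lists were not tested here, and the genes below are the 5 with the largest fold in each direction. Gata1 at 303 ± 105.04 CPM was at least 5610.3-fold higher, Rhag, a red cell membrane gene, at 558 ± 288 at least 10338-fold, Tspan33 at 298 ± 189 at least 5513-fold, Gfi1b at 293 ± 165 at least 5427-fold and Acss1 at 183 ± 123 at least 3380.2-fold higher. Adipoq at 964 ± 874 CPM in non-immunized CD200+ cells was at least 20141-fold lower in CD105+ cells, Wif1 at 431 ± 306 at least 9008-fold and Cavin2 at 317 ± 206 at least 6616-fold lower. Ibsp went from 6099 ± 1362 to 0.161 ± 0.235 CPM (log2 change -15.07, edgeR adjusted p = 8.02e-05), and Dmp1 from 2310.4 ± 3467 CPM to 3 counts, a ratio of 48248 with a 95% counting interval of 16510 to 233961, which falls to 12598 without library 2. The edgeR adjusted p of these 10 genes lay between 5.15e-05 and 0.00220. In all, edgeR called 1982 genes, 836 higher and 1146 lower (lowest adjusted p = 4.32e-05). DESeq2 called 3774, limma voom 4993, edgeR with RLE factors 2099 (669 higher, 1430 lower) and with spike-in library sizes 278 (167 higher, 111 lower), and without library 14 edgeR called 1308. With only the 2 groups fitted, edgeR called 2070, of which 1113 were higher and 957 lower. Groups did not overlap for 3603 genes, 24.0% of those tested, where chance gives 1.59%. RLE factors and spike-in sizes shifted the median log2 change by -0.26 and 1.37.

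Summed markers of other cell types give the background in each group, with 20 exact permutation tests over 10 lists. Erythroid markers summed to 98023 ± 86724 CPM in CD105+, 2169 ± 4607 in arthritic CD200+ and 4429 ± 4135 in non-immunized CD200+ cells, and differed between the arthritic populations (two-sided exact p = 0.00794, adjusted p = 0.0265). The CD105+ mean was 60516 without library 10, the non-immunized mean 2506 without library 4, and most of the arthritic CD200+ sum came from 1 library at 10408 CPM. Mural markers summed to 90.5 ± 126, 1514 ± 432 and 1055 ± 342 CPM in the same order, and skeletal muscle markers to 119 ± 42.8, 779 ± 396 and 484 ± 293, both with the same exact p and adjusted p between the arthritic populations. T and NK markers summed to 12.9 ± 5.21, 0 and 19.6 ± 25.2 CPM and differed in both comparisons (exact p = 0.00794, adjusted p = 0.0265), but most of each sum was 1 gene, Lck at 11.2 CPM in CD105+ and Nkg7 at 16.9 in non-immunized CD200+ cells, so the markers did not move as a set. B and plasma markers were at 27.0 ± 49.96, 8.50 ± 13.0 and 1749 ± 3362 CPM, and were lower in arthritic than in non-immunized CD200+ cells (exact p = 0.00794, adjusted p = 0.0265), with Igkc the most abundant at 1289 CPM. The last mean rests on library 3 at 6791 CPM, without which it was 67.7 ± 31.3 (unadjusted exact p = 0.0179). That of CD105+ cells rests on library 11 at 116 CPM, and was 4.71 without it. Macrophage markers at 1622 ± 3598, 135 ± 144 and 364 ± 455 CPM and neutrophil markers at 317 ± 535, 158 ± 159 and 2444 ± 3497 did not differ by more than the spread between libraries. Of these means, those of CD105+ cells rest on library 11, without which they were 13.0 and 79.8 CPM. The non-immunized means were 147 without library 4 for macrophage and 783 without library 3 for neutrophil markers. No difference beyond the spread was found either for osteoclast markers at 483 ± 86.1, 222 ± 133 and 399 ± 230.4 (population exact p = 0.0238, adjusted p = 0.0680), endothelial markers at 58.3 ± 11.6, 47.3 ± 55.5 (23.8 without library 5) and 18.7 ± 23.1, or Schwann markers at 76.2 ± 45.1, 62.4 ± 36.2 and 143 ± 97.4 CPM.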

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

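The tests of red cell RNA and of muscle fibres were chosen only after the result was seen, and the 2 further gene lists used here were chosen after Gata1, Klf1 and Pax7 had been seen to differ.

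A library was taken to lie far from its group when its gap to the nearest other library was a large part of the whole range of the group. Of 311 groups of values tested, 44 held such a library, where chance gives about 1 in 20, or 15.55. They comprised 1 library measure, 4 summed marker lists and 39 genes. Library 5 was low in 8 and library 1 high in 5. Many others are genes with counts in only 1 library of a group. Such groups reach the highest ratio by construction, so 44 against 15.55 is not a like comparison.

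In arthritic CD200+ cells, haemoglobin made up 1.07% of gene counts in library 9 (Wilson 95% interval 1.07 to 1.08) against 0.000490 to 0.0287% in the other 4. Library 5, with 87.4% spike-ins, was low for some bone and stromal genes, while its Spp1 level of 32416 CPM lay within the range of the group. It held Bglap at 26.3 CPM (others 615 to 906), Ibsp at 49.96 (3006 to 4376), Lepr at 58.1 (185 to 288), Rpl6 at 457 (620.1 to 656) and 0 counts of Dmp1 (217 to 280) and Wif1 (45.1 to 201). Its summed macrophage markers were 0 CPM (72.7 to 378), its Schwann markers 4.85 (61.2 to 104) and its Chodl level 1469.5 (430 to 487). Library 6 was high for Ccl19 at 151 CPM (38.7 to 47.5), low for Notch3 at 47.5 (87.0 to 110) and had 0 counts of Rrm2 (46.3 to 69.2). Library 7 was low for Spp1 at 17519 CPM (30167 to 36485). It was the only library of its group with counts of H2-DMa (5.81 CPM), Matn3 (18.05) and Ptprc (0.0755). Car1 had counts only in library 8 (0.137 CPM), and Clic5 (0.820) and Lgr5 (1.39) only in library 9.

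In non-immunized CD200+ cells, library 1 was high for the erythroid genes Epb42 at 28.6 CPM, Slc4a1 at 8.72 and Tspo2 at 8.72. Summed erythroid markers were highest in library 4 instead, at 10197 CPM against 4633 in library 1. Library 1 was also high for the mitotic genes Plk1 at 2.27 and Aurkb at 2.09. Library 2 had Schwann markers of 2.43 CPM (172 to 227), and Ptprc had counts only in library 4 (19.7 CPM).

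In CD105+ cells, library 10 was high for Car1 at 7321 CPM (1905 to 2792), Ndufa9 at 435 (274 to 286) and Bmp4 at 1.56, and low for Fbn1 at 2.45 (44.6 to 110). Library 11 had macrophage markers of 8058 CPM (4.24 to 20.1), Notch1 at 2.04 and Cebpa at 0.660. Library 12 was high for Col11a1 at 145 CPM (0 to 0.960), Tnmd at 16.4, Cd200 at 11.5 and Il6 at 0.575. Library 13 was high for Notch3 at 4.85 CPM (0 to 0.600), Kitl at 1.48, Grem1 at 1.20 and Alpl at 0.742, and library 14 for Dmp1 at 0.222 and Myod1 at 0.148.

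Erythroid transcripts in the CD105+ libraries are led by Hba-a1 at 34017 and Hba-a2 at 24494 CPM, although the sort excluded TER119 and CD45. If red cell RNA common to all libraries were the source, the ratio of 5 other erythroid genes to globin would lie in the range of the CD200+ libraries. It was 1.70 to 8.72 per 100 CPM of globin in CD105+ libraries against 0 to 2.36 in the 7 CD200+ libraries with at least 1000 globin counts (two-sided exact permutation p = 0.00758), but libraries 1 and 2 lie inside the CD105+ range, so this source cannot be told apart. Of a further list of 20 erythroid regulators and haem enzymes, none in the other lists, 13 rose in CD105+ cells (65%), against 4.79% of all genes and at most 6 in 10000 random lists, and arthritic CD200+ cells express 9 of the 20 at 10 CPM or more. Members of such a list tend to move together, unlike random genes, and it was written after Gata1 and Klf1 had been seen to differ. The random lists therefore do not weigh for or against a source. Nucleated erythroid precursors in the sort are a candidate source, not told apart here from other erythroid RNA. A biological erythroid programme of CD105+ cells stays open and untested.

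Myogenic transcripts in the CD200+ libraries might come from muscle fibres or from muscle progenitors carried into the sort. Fibre RNA would bring 13 fibre genes above Pax7, Myod1, Myf5 and Cdh15, but the median ratio in 9 CD200+ libraries was 0.193, and 8 of the 9 lay below 1 (library 7 at 1.22), which argues against fibres as the source. Of a further list of 12 muscle progenitor and myoblast genes, none in the other lists, 9 were past the threshold as lower in CD105+ cells (75%), against 6.48% of all genes and at most 5 in 10000 random lists. All 12 were at 10 CPM or more in CD200+ cells, led in the sorted groups by Peg3 at 562 ± 248 CPM. This list too was written after Pax7 had been seen to differ, and random genes do not move together as its members may. Its random lists therefore do not weigh for a source either. Muscle progenitors in the CD200+ sort are a candidate source, which the TER119, CD31 and CD45 gates would not remove. Expression by the skeletal cells themselves was not tested.

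DESeq2 called 224 genes in the arthritis comparison where edgeR called 0, with 915 at an unadjusted p under 0.05. Among them 93 (41.5%) had over 80% of the CPM of their higher group in 1 library, most often library 1, so single libraries could be the cause for part of them, and this cannot be told apart from a change shared by a group. Of 50 splits of the 9 libraries, 13 gave as many DESeq2 calls, the highest other 375, so chance is not excluded. A biological effect of arthritis on these genes stays open.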

How the results depend on the processing

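The settings without the 3 libraries over 80% spike-ins and with the genes of the filtered table were chosen only after the data were seen, as was following, one by one, only lists past the test and the lining list. Each result was checked in several settings, and the numbers here count these checks. A count was taken as the same within 1.5 times, whatever its balance of higher and lower genes. A fold change, list or spike-in difference was the same if it kept its direction and side of the threshold. Besides leaving out libraries, 72 checks of main results were the same, 11 counts moved further and 1 difference newly passed. Of the checks of other results 1624 were the same, 114 no longer passed, 58 newly passed and 21 reversed. The cause was not tested for any of those below except where stated. With an estimated correlation, 0 lists passed in the arthritis and 0 in the population comparison, and with fry 0 in arthritis. DESeq2 called 224 genes (80 higher, 144 lower) in arthritis, 3274 between populations and 3774 in the joint comparison, with Eng at 3.64 between populations (adjusted p = 0.0363, over all settings 0.0363 to 0.295) and Thy1 at -0.0134 in arthritis. Limma voom called 4 (3 higher, 1 lower), 4624 and 4993 genes, with Btg2 at 0.0399, Itgav at -1.45 and Thy1 at -0.33 in arthritis and Thy1 at 0.72 between populations. Spike-in library sizes left 545 genes between populations and 278 in the joint comparison, and gave 0.0587 for mt-Cytb, 0.16 for mt-Atp6, 1.08 for Itgav and 1.34 for Thy1 between populations, where the median of all genes shifted by 1.23, and -1.19 for Itgav and -0.61 for Thy1 in arthritis. Thy1 in arthritis, at 0.02 in the main result, was -0.0146 with RLE factors, -0.10 without a filter and -0.0186 with the genes of the filtered table. Without the 3 libraries, Btg2 was 0.0940, Itgav -2.38 and Thy1 -0.90 in arthritis, and Itgav 0.13 and Thy1 0.35 between populations. The lining list reversed, passing neither way, with limma fry in arthritis (adjusted p = 0.938) and with limma camera on the compared groups alone between populations (adjusted p = 0.671).

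Leaving out 1 library at a time gave 0 to 2 genes (2 without library 3) and 6 to 12 lists in arthritis, 1090 to 1794 genes between populations and 1308 to 2353 in the joint comparison, both lowest without library 14. Log2 changes in arthritis ranged from -2.01 to 0.11 for Btg2 (reversed without library 2), -1.73 to 1.19 for Itgav, -0.88 to 0.84 for Thy1 and -8.88 to 1.43 for Ptprc (reversed without library 4, the only one of its group with counts), and between populations from -1.13 to 0.73 for Thy1. The immediate early list ranged from 3.50e-06 to 0.953 and the lining list from 0.422 to 0.994 in arthritis. The spike-in share differed between CD200+ groups by -3.08 to 12.5 percentage points (reversed without library 1, 5 or 6). In these runs 127 checks of main results were the same, 6 counts moved further and 3 main differences, all of the spike-in share, reversed. Of the checks of other results 2408 were the same, 160 no longer passed, 14 newly passed and 15 reversed. No paired analysis was possible, since the labels do not say whether samples of different groups came from the same mice. The sample numbers run through all groups and do not settle it. Limma on normalized values was not run, since the table holds raw counts. Depth limits what a count of 0 shows to 0.162 to 1.03 CPM per library, and library 6, with the fewest gene counts, sets the upper end.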

Other observations

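The further erythroid and muscle lists below were chosen only after the result was seen, while the counts over other splits of the libraries were planned.

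Of the further erythroid list, Trim10 stood at 152 ± 49.6 CPM in CD105+ cells with 0 counts in arthritic CD200+ cells, at least 2638-fold higher (edgeR adjusted p = 0.000187). The haem synthesis genes Fech, Urod and Ppox stood at 644 ± 281, 614 ± 204 and 253 ± 67.0 CPM against 65.8 ± 26.5, 35.2 ± 20.3 and 24.5 ± 20.1 (edgeR adjusted p = 0.000322, 0.000855 and 0.00150). The erythropoietin receptor gene Epor at 170.1 ± 60.03 and Tal1 at 36.4 ± 13.6 CPM had 0 counts in arthritic CD200+ cells, at least 2946-fold and 629.9-fold higher (edgeR adjusted p = 0.0126 and 0.0265). Ank1 did not differ by more than its spread (log2 change -0.13, edgeR adjusted p = 0.930). Of the further muscle list, Fgfr4 at 111 ± 24.8 and Myog at 173 ± 162 CPM in arthritic CD200+ cells had 0 counts in CD105+ cells, at least 2322-fold and 3615-fold lower (edgeR adjusted p = 0.000115 and 0.0404). Peg3 fell by 7.08, Megf10 by 4.79 and Chrna1 by 7.10 on the log2 scale (edgeR adjusted p = 0.00209, 0.0141 and 0.0155), while Cd82 at 64.3 against 92.6 CPM did not pass (adjusted p = 0.734).

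Other splits of the same libraries into groups of the same sizes show what chance gives. Between the arthritic populations, 1 of 100 splits, the real one, gave 1692 genes, the highest other 14. This is the smallest share that 100 splits can give. An arbitrary grouping is thus unlikely to give that count if the samples are independent, which the labels do not settle. In the joint comparison 1 of 100 gave 1982 genes, the highest other 481, with the same reading. In the arthritis comparison all 100 splits gave at least the 0 genes of the real one, which no split can miss, the highest other 46, and 15 of 100 gave at least its 915 genes at an unadjusted p under 0.05, the highest other 1538, so chance is not excluded. As many lists as the 11 of the arthritis comparison came from 4 of 100 splits, the real one included, the highest other 12. This is under the limit of 5% fixed beforehand, but close to it, and not every distinct split was run. Chance is therefore not firmly excluded for the number of lists with the preset correlation, nor for any 1 list. The number was 0 with an estimated correlation, 0 with fry and 6 without library 9, and the splits were not run for those settings. The median of the 99 other splits was 6 lists, so several lists pass with the preset correlation in arbitrary splits too. As many as the 19 lists between populations came from 5 of 100 splits, the highest other 22 and the median of the others 9, so chance is not excluded for that number.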
